A study of Carassius auratus with 9 samples.

How the data were processed

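RNA sequencing was carried out on back skin of celestial goldfish (Carassius auratus) aged 4 months, with brown, white or yellow skin and 3 biological replicates of each color, per the labels. Total RNA was extracted and libraries were made with a SMARTER mRNA-Seq kit, per the labels' protocols. HISAT2 and StringTie are named in the submitters' processing notes, without versions. The strand setting of the counting and the counting rule for reads that match more than 1 place are not given in the sources used here. The authors deposited 1 file per library with an FPKM value (fragments per kilobase of gene, scaled to the library) for each of 74297 genes, together with the gene's position, length and product name.

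The genome build is not named in the files. Of the gene IDs, 72068 matched the NCBI RefSeq gene table of assembly ASM336829v1, and 72059 of these had the same start position, so coordinates are given as the files give them and chromosome numbers are those of that assembly. Genes on unplaced sequence are described as such. A further 2229 rows had no gene name and took between 0.862% and 1.49% of a library's reads; they were kept, as they carry positions and IDs of the authors' assembly.

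The depth behind the FPKM values was recovered from the values themselves. FPKM multiplied by gene length fell on whole multiples of 1 step per library for 100% of the nonzero values, within a tolerance of 0.001 reads. The recovered counts summed to between 13772601 and 17359648 per library. The library denominators that the authors' values imply were 0.675 to 1.39 times the counted reads, so that FPKM multiplied by length in kilobases summed to between 719638 and 1482470, depending on the library. In a chi-square comparison of the counts over all 36 pairs of libraries, the most similar pair, yellow 1 and yellow 2, still differed by 26.7 per gene, and the most similar pair of different colors by 50.5, so no library was a copy of another. A single read on a gene of 1 kilobase is worth 0.0448 to 0.0891 FPKM. Folds between colors were computed from reads pooled over the 3 libraries of a color and divided by the summed denominators. Where a color had no read, the fold is a lower bound against a floor of 3 reads over the group. Where it had 1 to 3 reads, the ratio has an exact 95% binomial counting interval. Intervals and floors cover counting error only, not the spread between biological replicates.

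The main test was limma 3.58.1 in R 4.3.3 (limma-trend) on log2(FPKM + 1), with all 9 libraries in 1 fit, skin color as the only term, and 27420 genes with an FPKM of at least 1 in at least 3 libraries. Fold changes from this fit are on the log2(FPKM + 1) scale, which understates the change of genes with low values. The 3 contrasts between colors were tested two-sidedly with Benjamini-Hochberg adjustment at 0.05, and a moderated F test covered the 3 colors together. Because the unit is FPKM, no count model was used as the main test. Voom (limma) on the recovered reads was an alternative chosen after seeing the data. TPM, for comparison, was computed from the FPKM, since FPKM is the unit of the files used here.

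The 20 gene lists (pigment pathways, markers of the cell types that back skin can hold, and handling and metabolic genes) were fixed before the data were examined, and 19 had at least 3 tested members. The ionocyte list had 1. They were tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry beside it. Members were also adjusted over the list alone. The rule for named genes, also fixed before the data were examined, takes per comparison the 5 largest rises and 5 largest falls with a product name among genes that pass and whose libraries do not overlap (or the 10 smallest p where fewer than 10 pass), up to 4 passing members of each list, and the tested copies of 13 pigment genes. With 18 tested copies, those pigment genes are given as reads summed over copies, with the number of copies that passed.

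The white libraries serve both comparisons against white, so overlap was set beside 100 simulations of unchanged groups made by permuting the libraries' deviations from their group means. The gene test was tried on simulated counts drawn from the real means, spreads and denominators, with 200 genes changed in brown. For brown against white, over 27211 genes, it recovered 21 of 100 genes changed 4-fold and 70 of 100 changed 16-fold, with 13 false calls. For yellow against white, camera called the 1 list that had been raised and 0 others. The simulated genes were drawn independently, while the real skeletal muscle list had an estimated inter-gene correlation of 0.713. The simulation therefore does not show how often camera calls real lists falsely. Alternatives covered the pseudocount (0.1 and 0.5), no filter and a filter at 5 FPKM, TPM, median-of-ratios and quantile scaling, array weights, robust empirical Bayes, a replicate block, the 6 libraries compared, summed copies with the same product name, a minimum of a 2-fold change, and each library left out. Added after seeing the data were voom, a fit without the 3 libraries numbered 3, and the muscle score, alone or with the keratinocyte score, as a covariate. A score is the median over a list's tested members of their centered log2 values. Figures were drawn with matplotlib 3.10.9.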

Results

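Back skin transcriptomes of celestial goldfish, a breed of Carassius auratus, were compared between brown, white and yellow fish to find genes related to skin pigment. Each color had 3 biological replicates, and the fish were 4 months old. Between 13772601 and 17359648 reads per library were counted on genes. Goldfish carry many duplicated genes, and values of near-identical copies are uncertain because the handling of shared reads is not given in the sources used here.

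Libraries differed widely in muscle transcripts within each color. Genes of the skeletal muscle list took 3.86%, 1.53% and 12.5% of reads in brown 1, 2 and 3, 1.35%, 7.4% and 20.7% in white 1, 2 and 3, and 0.157%, 0.545% and 14.9% in yellow 1, 2 and 3. The libraries numbered 3 had the highest share and the lowest of the denominators implied by the FPKM in each color. The first principal component held 45.2% of the variance, and 20 of its 50 strongest genes were on the muscle list. Correlations between log2 profiles of the same color ranged from 0.711 to 0.947, and those between colors from 0.686 to 0.933.

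**Figure D1:**
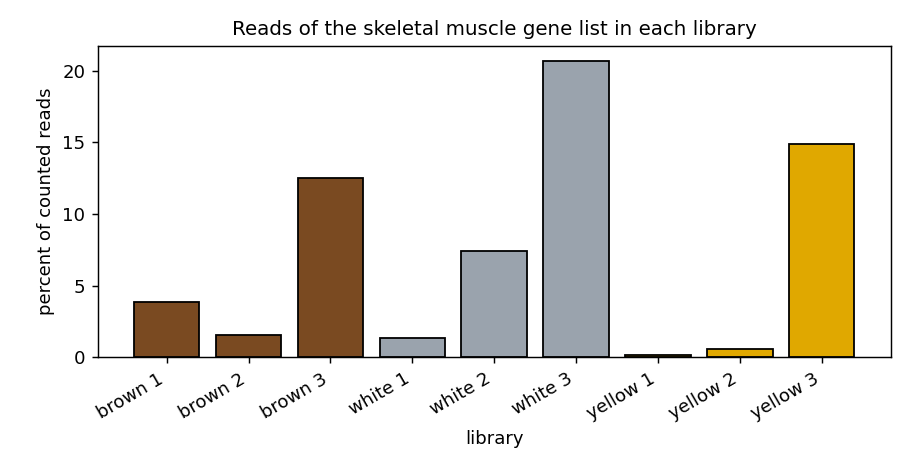
Percent of counted reads on genes of the skeletal muscle list (vertical axis, from 0) in each of the 9 libraries (horizontal axis, bars colored by skin color). The share ran from 0.157% in yellow 1 to 20.7% in white 3, and each color held both low and high libraries.

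The comparison of brown with white skin asks which genes differ where dark pigment is present. Putative defense protein 3 (LOC113094292, unplaced sequence, 60766 to 62666) rose from 0 reads in all 3 white libraries to 9.53 ± 3.47 FPKM in brown (SD, n = 3), at least 133-fold higher against a floor of 3 reads over the group (limma adjusted p = 0.0111). Without white 1 or white 2 the bound was 75.6 or 86.9. A seipin-like gene (LOC113045120, chromosome 27, 3480392 to 3485304), whose relatives act in lipid droplet formation, rose from 0.0442 ± 0.0517 to 27.8 ± 22.5 FPKM, with 3 reads in white and a ratio of 841 (95% counting interval 288 to 4080; limma adjusted p = 0.0244). The ratio was 480 without brown 2, 477 without white 1 and 1970 without white 3 (95% counting interval 354 to 78000). The 5 seipin-like copies summed to 5.24 ± 1.15 FPKM in white and 53.9 ± 48.2 in brown, a log2 change of 2.80 ± 0.54 (SE) that did not pass (limma adjusted p = 0.548). A retinol dehydrogenase 12-like gene (LOC113042262, chromosome 24, 10404792 to 10407468) rose 41.4-fold, from 0.517 ± 0.328 to 17.8 ± 7.74 FPKM (limma adjusted p = 0.0244). The sum of its 10 copies had a log2 change of 1.40 ± 0.36 (SE), which did not pass (limma adjusted p = 0.799). A copy of actin-related protein 2/3 complex subunit 4 (LOC113111009, chromosome 11, 10754558 to 10757665) rose 36.5-fold to 10.8 ± 4.96 FPKM (limma adjusted p = 0.0244). The 5 copies summed to 90.5 ± 23.7 FPKM in white and 84.3 ± 32.8 in brown, a log2 change of -0.15 ± 0.42 (SE) with a limma adjusted p = 0.936. The rise of the single copy is small beside that spread, so the sum cannot speak for or against it. Of the 20 white reads of LOC113111009, 19 were in white 1, without which the ratio was 414 (95% counting interval 74 to 16400).

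Genes that fell in brown were led by coagulation factor XIII A chain-like copies, which encode the subunit of a transglutaminase. LOC113042740 (chromosome 24, 7353191 to 7366546) had 24 ± 10.3 FPKM in white and 0.182 ± 0.0898 in brown, 134-fold lower. LOC113066051 (chromosome 49, 3572535 to 3585956) had 14.8 ± 6.32 and 0.0481 ± 0.0465 FPKM, 250-fold lower. LOC113042211 (chromosome 24, 7398476 to 7414168) had 6.58 ± 2.9 FPKM in white and no read in brown, at least 276-fold lower. A sterile alpha motif domain-containing protein 7-like gene (LOC113119323, chromosome 2, 19416225 to 19423276) had 14.5 ± 8.04 FPKM in white and no read in brown, at least 569-fold lower. The limma adjusted p was 0.0164 for LOC113066051 and 0.0244 for the other falling genes. Without brown 1 the fold was 617 for LOC113066051 (95% counting interval 171 to 5100), at least 152 for LOC113042211 and at least 312 for LOC113119323. Summed over the 8 annotated factor XIII A copies, the log2 change was -1.47 ± 0.41 (SE), which did not pass (limma adjusted p = 0.799). With a pseudocount of 0.1 the limma adjusted p was 0.21 for LOC113042740, 0.0637 for LOC113066051 and 0.273 for LOC113042211, so these calls were lost.

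In all, limma called 6 genes higher and 4 lower in brown than in white among 27420 tested, and the other called genes were unannotated transcripts on chromosome 2 at 25874338 to 25878146 and 19678391 to 19678871. At an unadjusted p under 0.05 there were 1569 genes, where 1371 are expected by chance, and the 3 libraries of each color did not overlap for 10.9% of genes, where chance gives 10%. Voom on the recovered reads called 0 genes, with 1371 at an unadjusted p under 0.05. The count fell to 0 without brown 1, white 1, white 2 or white 3 and without the 3 libraries numbered 3, to 4 without brown 2, brown 3 or yellow 1, and to 3 without yellow 2. With a pseudocount of 0.1 the split was 10 higher and 1 lower, with 5 of the 10 genes kept. With TPM the split was 1 higher and 4 lower, with the median gene shifted by -0.20 on the log2 scale.

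Genes of the melanin synthesis and melanosome list had a median log2 change of 0.79 in brown against white. No member passed over all genes, 9 of its 22 tested members rose when adjusted over the list alone, and 0 fell. Camera called the list up (adjusted p = 6.72e-08), but the adjusted p = 0.258 with an estimated correlation. A copy of tyrp1, which encodes a melanin synthesis enzyme (LOC113106593, chromosome 1, 29331820 to 29340266), had 2.9 ± 2.42 FPKM in brown and no read in white, at least 134-fold higher (limma adjusted p = 0.0123 over the list alone and 0.686 over all genes), and the bound was 68.6 without brown 2, 76 without white 1 and 87.4 without white 2. The melanosome matrix gene pmel (LOC113069261) had 2.21 ± 1.79 and 0.06 ± 0.104 FPKM (0.0399 over the list alone). Melanophilin-like LOC113096918, which links melanosomes to their motor, had 4.71 ± 5.24 and 0.165 ± 0.138 FPKM (0.0458 over the list alone). Without brown 2 the brown means were 1.52 FPKM for LOC113106593, 1.18 for LOC113069261 and 1.69 for LOC113096918, and without white 2 the white means of the last 2 were 0 and 0.0864. Without brown 2 the count of rising members over the list alone was 1 in place of 9, and it was 2 without white 1, white 2 or white 3 and 4 without yellow 1. Without any 1 of the brown libraries LOC113106593 was below the filter on low values and was not tested.

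Among the other lists, camera called interferon response (adjusted p = 0.000491) and keratinocytes (0.00971) up and dermal fibroblasts and scale-forming cells (1.47e-05), adipocytes (0.000491) and endothelium (0.00532) down in brown against white. The adjusted p with an estimated correlation was 0.826, 0.831, 0.826, 0.738 and 0.738 in that order. Of 23 interferon response members, 2 rose when adjusted over the list alone, both interferon-induced GTP-binding protein Mx-like copies. LOC113043304 had 15.8 ± 8.24 FPKM in brown and 1.81 ± 1.53 in white, and LOC113071816 had 11.7 ± 1.01 and 2.67 ± 2.74. Over the list alone 0 members rose without brown 2 or white 2, 1 without brown 1, white 3 or yellow 1, and 8 without brown 3. Without white 1 the white mean of LOC113071816 was 1.12 FPKM, and without white 3 that of LOC113043304 was 1.11. No member of the keratinocyte, dermal, adipocyte or endothelium lists passed either adjustment. The keratinocyte score was 0.272 ± 0.0519 in brown and -0.42 ± 0.879 in white, and the muscle score 0.0857 ± 1.3 and 0.868 ± 2.27. The other 13 lists were not called, with skeletal muscle the nearest (camera adjusted p = 0.104). Camera's direction differed in sign from the median of -0.12 for purine synthesis and iridophore (mean -0.01), -0.02 for pigment cell regulators and 0.06 for immune cells.

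The comparison of yellow with white skin asks which genes differ where yellow pigment is present. The seipin-like gene rose to 60 ± 13.9 FPKM in yellow (ratio 1730, 95% counting interval 592 to 8400; limma adjusted p = 0.00476), putative defense protein 3 to 23 ± 1.56 FPKM (at least 326-fold; adjusted p = 0.000488) and the retinol dehydrogenase 12-like gene 78.5-fold to between 22.4 and 42.6 FPKM in the 3 yellow libraries (adjusted p = 0.00531). The seipin-like copies summed to 92.4 ± 26.3 FPKM in yellow, a log2 change of 3.88 ± 0.54 (SE), and the retinol dehydrogenase 12 copies had a summed log2 change of 2.21 ± 0.36, and neither sum passed (limma adjusted p = 0.114 and 0.256). A perilipin-3-like gene (LOC113059134, chromosome 41, start 17859669), of a family that coats lipid droplets, rose 134-fold from 0.102 ± 0.0721 to 11.2 ± 3.18 FPKM (adjusted p = 0.00894). A copy like melanoma antigen recognized by T-cells 1, a melanosome protein also called mlana (LOC113081155, unplaced sequence, 144941 to 148752), rose from 0.0656 ± 0.114 to 12.1 ± 5.69 FPKM (ratio 173, 95% counting interval 59 to 843; adjusted p = 0.0149). The triglyceride synthesis gene dgat2 (LOC113054403, chromosome 35, 11827513 to 11837386) had no read in white and 7.7 ± 2.34 FPKM in yellow, at least 327-fold higher (adjusted p = 0.0149). The sum of the 2 mlana copies had a log2 change of 4.20 ± 0.43 (SE), which passed (limma adjusted p = 0.0105). The summed log2 change was 1.77 ± 0.37 (SE) for the 2 perilipin-3 copies and 0.41 ± 0.66 for the 5 dgat2 copies, and neither passed (limma adjusted p = 0.534 and 1). Without white 1 the ratio was 981 for the seipin-like gene, 98.2 for mlana (95% counting interval 33.4 to 478) and 83.5 for perilipin-3, and the bound 185 for both putative defense protein 3 and dgat2. Without white 2 the bounds were 212 for putative defense protein 3, 213 for dgat2 and 113 for mlana, and without white 3 the seipin-like ratio was 4060 (95% counting interval 729 to 160000).

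Coagulation factor XIII A chain-like copies fell in yellow as well. LOC113042740 was at 0.831 ± 1.39 FPKM in yellow, LOC113066051 at 0.479 ± 0.622 and LOC113042211 at 0.222 ± 0.385, which is 23.4-fold, 26.8-fold and 23.7-fold lower than in white (limma adjusted p = 0.0426, 0.0149 and 0.0426). Of their yellow reads, yellow 1 held 141, 81 and 38, yellow 2 none, and yellow 3 held 2, 10 and 0. Without yellow 1 the folds were 1040 (95% counting interval 288 to 8600), 152 and at least 187, and without yellow 2 they were 13.9, 15.9 and 14.1. Summed over the 8 copies the log2 change was -0.92 ± 0.41 (SE), which did not pass (limma adjusted p = 1). With a pseudocount of 0.1 none of the 3 copies passed (limma adjusted p = 0.222, 0.184 and 0.461), and with 0.5 LOC113042740 (0.0812) and LOC113042211 (0.0782) did not.

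**Figure D2:**
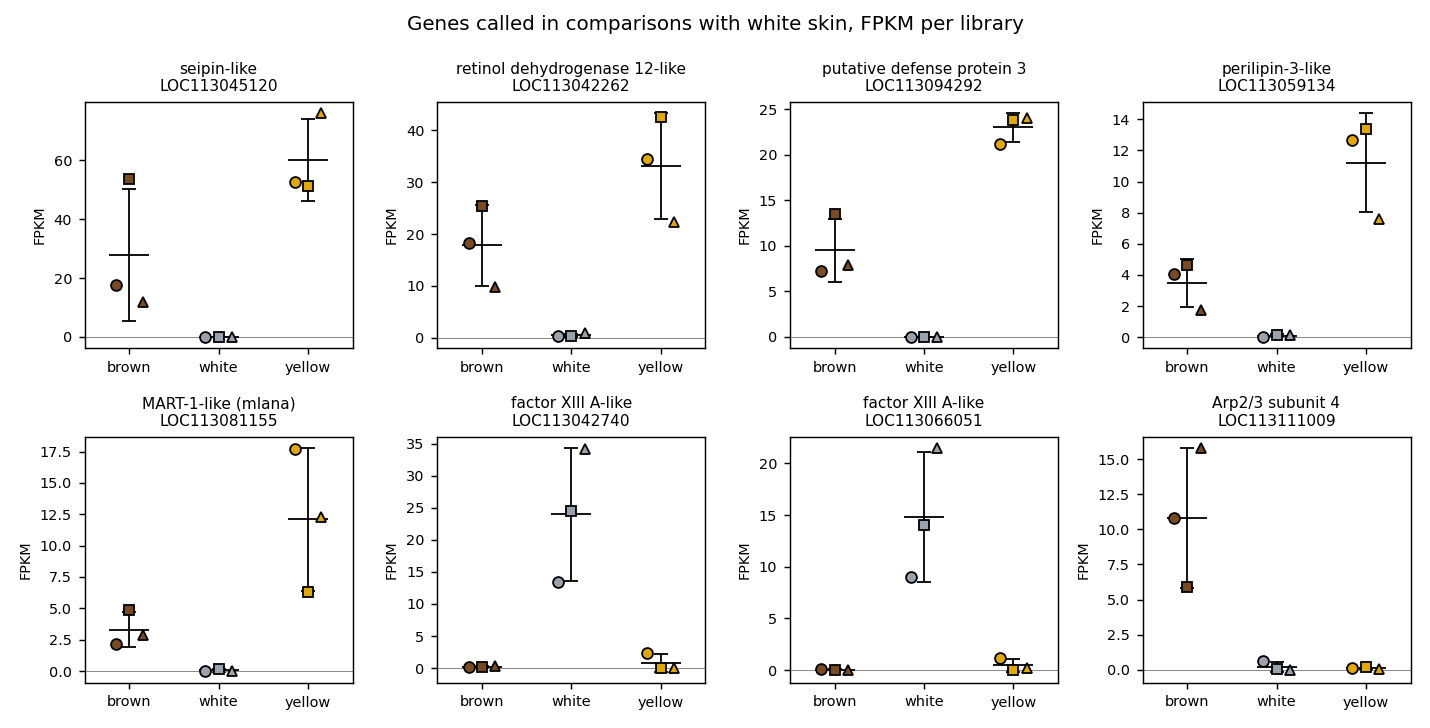
FPKM (vertical axes, linear) of 8 genes called in a comparison with white skin, by skin color (horizontal axes). Symbols are libraries (circle, square and triangle for replicates 1, 2 and 3), and black lines are the mean with SD, n = 3. In white the 5 genes shown first averaged at most 0.517 FPKM, and both coagulation factor XIII A chain-like copies were highest there.

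Limma called 9 genes higher and 3 lower in yellow than in white, the others being opsin-5-like LOC113098145, uncharacterized LOC113116617 and the unannotated transcript on chromosome 2 at 25874338. The summed log2 change of the 16 opsin-5 copies was 1.91 ± 0.31 (SE), which did not pass (limma adjusted p = 0.256). At an unadjusted p under 0.05 there were 960 genes, fewer than the 1371 expected by chance, and the 3 libraries of each color did not overlap for 9.64% of genes, where chance gives 10%. Voom on the recovered reads called 0 genes, with 839 at an unadjusted p under 0.05, and array weights, which gave yellow 1 a weight of 10.1, called 437. The count was 7 without brown 1, brown 3 or yellow 1, 5 without white 1 or white 3, 2 without white 2 and 6 without the 3 libraries numbered 3, and with TPM the split was 8 higher and 1 lower. With a pseudocount of 0.1 it was 12 higher and 0 lower, and with 0.5 it was 10 higher and 1 lower.

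On the melanin synthesis and melanosome list, 1 of 22 members rose over all genes in yellow, 6 rose when adjusted over the list alone and 0 fell. Camera called it up (adjusted p = 1.82e-12), with an adjusted p = 0.091 with an estimated correlation, and fry gave an adjusted p = 0.0282. Carotenoid uptake and metabolism was called up (camera adjusted p = 0.00141), with an adjusted p = 0.441 with an estimated correlation. Of its 16 members, 1 rose over all genes and 2 over the list alone, dgat2 and beta,beta-carotene 15,15'-dioxygenase-like LOC113051774, a carotene-cleaving enzyme, with 2.63 ± 1.67 FPKM in yellow and 0.0152 ± 0.0264 in white, where both reads were in white 1. Over the list alone 1 member rose without yellow 1 or yellow 2 and 4 without brown 2. Pteridine synthesis and xanthophore was not called by camera (adjusted p = 0.295). Fry's test for changes in either direction called 3 lists, with an adjusted p = 0.00355 for melanin synthesis and melanosome and 0.000711 for each of the carotenoid and pteridine lists. GTP cyclohydrolase 1-like LOC113056131, of the enzyme that starts pteridine synthesis, had 4.13 ± 2.53 and 0.0173 ± 0.0152 FPKM, and Pax-7-like LOC113068849 had 7.37 ± 2.6 and 0.493 ± 0.399 (limma adjusted p = 0.00214 for each over the list alone).

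Among the other lists, camera called keratinocytes (adjusted p = 0.00516), mucous cells (0.00169), immune cells (0.0033) and interferon response (2.67e-06) up in yellow against white. It called skeletal muscle (1.51e-11), dermal fibroblasts and scale-forming cells (0.00815), adipocytes (0.000142), Schwann cells and neurons (0.00381), endothelium (0.00815) and glycolysis (0.0393) down. None was called with an estimated correlation, where the adjusted p was 0.517 for keratinocytes, mucous cells, immune cells, interferon response, skeletal muscle, Schwann cells and neurons, and endothelium, 0.57 for dermal fibroblasts and glycolysis, and 0.49 for adipocytes. The muscle score was -1.01 ± 2.96 in yellow and 0.868 ± 2.27 in white. With the muscle score as a covariate, camera called 3 lists in place of 12, and without yellow 2 it called 6. No member of these 10 lists passed either adjustment. Cell cycle was the nearest of the 7 lists not called (0.139).

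Pigment gene reads, summed over annotated copies and divided by the authors' denominators, are given in CPM, as values with no test of the sums. The gene tyrp1 was at 13.5 in brown, 0.0582 in white and 0.507 in yellow, pmel at 8.71, 0.311 and 15.1, and the tyrosinase gene tyr at 3.55, 0.602 and 3.75. The melanocortin receptor gene mc1r was at 2.18, 0.679 and 8.95, slc45a2 at 3.12, 0.602 and 3, and dct at 1.18, 0.0388 and 0.0751. Copies annotated like gch2 were at 4.55, 2.93 and 13.7, scarb1 at 20.7, 12.9 and 31.5, and pnp4a at 60.9, 31.7 and 59.7. The untested copies summed under gch2 carry the product name GTP cyclohydrolase 1-like, and those under pnp4a purine nucleoside phosphorylase-like. Both sums may thus include related genes. The gene oca2 was at 1.02, 0.0776 and 0.0375, and csf1r at 29.8, 35.7 and 47.8. The gene mitf, a regulator of pigment cells, was at 12.5, 13.8 and 12.7, and the receptor gene kit at 13, 15.2 and 16.9. Single libraries carried much of several values, and over libraries brown averaged 1.09 ± 1.52 for oca2 and 1.15 ± 1.4 for dct, and yellow 3.86 ± 4.2 for slc45a2 (SD, n = 3). Without brown 2 the brown values were 2.21 for tyr, 7.63 for tyrp1, 0.477 for dct, 5.07 for pmel, 0.179 for oca2 and 1.76 for slc45a2, and without brown 1 they were 20.7 for tyrp1, 1.78 for oca2 and 1.45 for mc1r. Without yellow 1 the yellow values were 2.41 for tyr and 9.32 for pmel, and without yellow 3 slc45a2 was at 1.44. Without white 1 the white values were 5.93 for kit and 1.85 for gch2, and without white 2 mc1r was at 0.298. The white values of tyrp1, dct and oca2 and the yellow value of oca2 rested on 3, 2, 4 and 2 reads, and with 1 library left out they ran from 0.0298 to 0.103, 0 to 0.0596, 0 to 0.119 and 0 to 0.0603. Of the 46 annotated copies 18 were tested. Limma called 0 of them over all genes in each comparison, with 6 at an unadjusted p under 0.05 in brown against white, 5 in yellow against white and 3 in brown against yellow, and voom called 0.

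**Figure D3:**
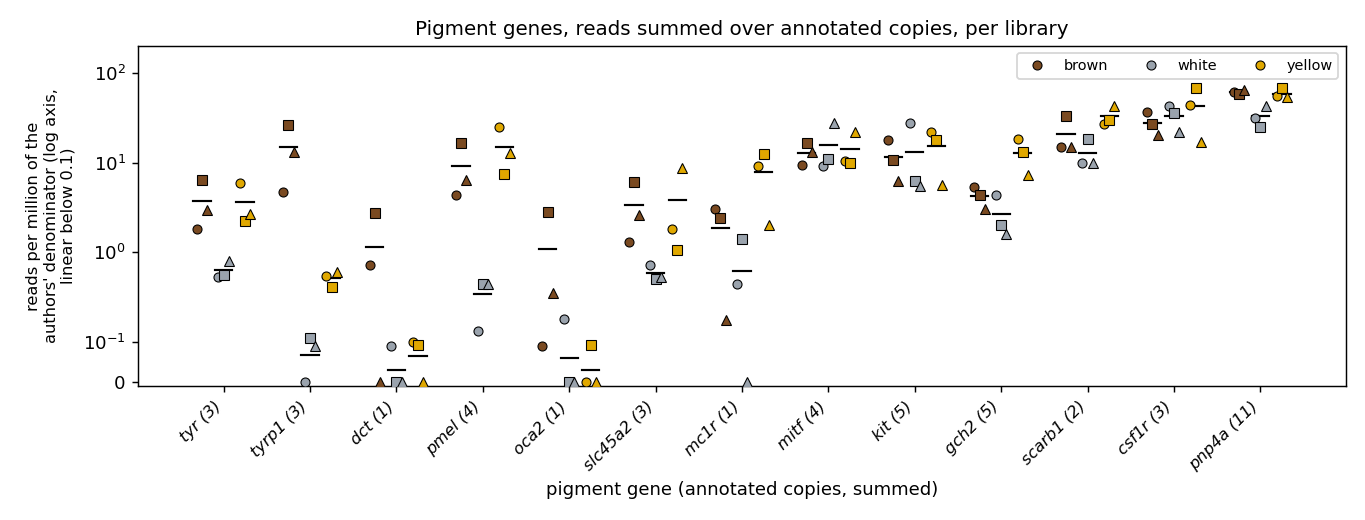
Summed reads over the authors' denominator, in CPM (vertical axis, log scale, linear below 0.1) of 13 pigment genes (horizontal axis, with the number of annotated copies summed). Symbols are libraries (circle, square and triangle for replicates 1, 2 and 3) and black lines are means over n = 3. By pooled reads tyrp1 averaged 13.5 in brown, 0.0582 in white and 0.507 in yellow. The mitf sum was at 12.5, 13.8 and 12.7, though its 4 copies differed.

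The comparison of brown with yellow asks which genes differ between the pigmented skins. Limma called 0 genes, with 457 at an unadjusted p under 0.05, where 1371 are expected by chance, and voom called 0, with 301. The libraries did not overlap for 5.22% of genes, where chance gives 10%. The smallest p belonged to genes that did not pass. Actin-related protein 2/3 complex subunit 4 LOC113111009 had 10.8 ± 4.96 FPKM in brown and 0.114 ± 0.0529 in yellow (limma adjusted p = 0.109), and LOC113119323 had no read in brown and 8.84 ± 5.09 FPKM in yellow (adjusted p = 0.462), which passed with a pseudocount of 0.1 (limma adjusted p = 0.00958). For the other 8 the limma adjusted p was 1. Transcription elongation factor A protein 3-like LOC113059190 had 5.33 ± 3.14 FPKM in brown and 0.0854 ± 0.0212 in yellow, putative homeodomain transcription factor 1 LOC113110989 had 2.15 ± 0.849 and 0.124 ± 0.0919, cep95 had 4.74 ± 1.65 and 0.51 ± 0.788, and hsd17b8 had 2.63 ± 0.701 and 0.598 ± 0.247. The rest were dgat2 and 3 unannotated transcripts, at 25874338 and 19678391 on chromosome 2 and at 391795 on unplaced sequence. Adjusted over the list alone, 1 melanin list member was higher in brown, tyrp1 LOC113106593 (0.0257), and 1 lower, mlana-like LOC113081155 (0.0257). Neither passed without yellow 1, and mlana did not without brown 1 or brown 3, while tyrp1 was below the filter on low values, and so not tested, without any 1 of the brown libraries. There were 2 higher without yellow 3 and 2 lower without yellow 2. On the carotenoid list the dgat2 copy LOC113054403 was lower in brown (0.00328), at 1.33 ± 0.875 against 7.7 ± 2.34 FPKM, and its brown mean was 0.882 without brown 2. The 5 dgat2 copies summed to 18.9 ± 1.68 FPKM in brown and 28.2 ± 16.8 in yellow, a difference within the spread of the yellow sum.

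Camera called skeletal muscle (adjusted p = 1.76e-06), heat shock and immediate early genes (0.0151) and the mitochondrial genome (0.00191) up in brown against yellow. It called pteridine synthesis and xanthophore (0.0235), carotenoid uptake and metabolism (0.0235), mucous cells (0.0235), dermal fibroblasts and scale-forming cells (0.00318), immune cells (0.00038) and cell cycle (0.000522) down. The adjusted p = 0.688 with an estimated correlation for heat shock, pteridine, carotenoid and immune cell lists, and 0.73 for the other 5. The muscle score was 0.0857 ± 1.3 in brown and -1.01 ± 2.96 in yellow. Glycolysis was the nearest of the 10 lists not called (0.163), and interferon response, called in neither direction, had a median of -0.05 and a mean of 0. Without yellow 1 camera called 1 list in place of 9, without brown 3 it called 3, and without brown 1 it called 5. For brown against white it called 3 lists without brown 1 and 10 without brown 3 or white 1, in place of 6.

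Across the 3 colors the moderated F test of limma called 13 genes, with 939 at an unadjusted p under 0.05, where 1371 are expected by chance, and voom called 0. The count was 0 without the 3 libraries numbered 3, 3 without brown 1, 6 without brown 3 or yellow 2, 8 without yellow 1, and 2 without white 1, white 2 or white 3. The comparisons against white shared 4 rising and 3 falling genes, where independent lists would share 0.00197 and 0.000438. Simulated unchanged groups against shared controls gave a median overlap of 0 and at most 3. Fold changes of the 27420 genes correlated at 0.678, beside a simulated median of 0.529, and their covariance was 0.198 beside a simulated median of 0.126, a difference of 0.072. The observed covariance lay within the range of -0.067 to 0.489 that held 95% of the simulated values. With 3 white libraries the controls could not be split, so part of the excess may come from the shared controls. The overlap was 0 without brown 1, white 1, white 2 or white 3 and without the 3 libraries numbered 3, 2 without yellow 2, 3 without brown 2, and 4 without brown 3 or yellow 1.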

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

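Voom, the fit without the libraries numbered 3 and the covariate fits were chosen after seeing the data. Causes were not tested except where fewer libraries or genes enter. In the order brown against white, yellow against white, F test and overlap, the counts of 10, 12, 13 and 7 genes became 2, 5, 2 and 2 without a filter, 5, 5, 5 and 4 at 5 FPKM, 16, 437, 157 and 14 with array weights, 0, 0, 0 and 0 with voom, 0, 6, 0 and 0 without the libraries numbered 3, and 0, 6, 2 and 0 with muscle and keratinocyte scores. TPM gave 5 for brown against white and an overlap of 2, and summed copies gave 3 and 4 genes. Brown against yellow gave 1 gene with a pseudocount of 0.1 and 8 with array weights. The replicate block gave 3, 6, 7 and 2. Same-numbered libraries correlated from -0.302 to 0.766, 7 of 9 pairs were over 0.1 and 5 of 9 libraries correlated best with their own number. By the rule that every pair be over 0.1, the numbers were not taken to pair the libraries. All pairs numbered 1 or 3 were positive, and the libraries numbered 3 had the highest muscle share and lowest denominator of each color, so a shared dissection or batch of those, not given in the sources used here, stays open. The remaining settings kept these counts within 1.5 times, with splits of 10 higher and 1 lower and 12 higher and 0 lower at a pseudocount of 0.1, where the falling factor XIII A copies no longer passed. Leaving out 1 library gave 0 to 14 genes for brown against white, 2 to 12 for yellow against white, 0 for brown against yellow, 2 to 12 for the F test and 0 to 7 for the overlap. For lists it gave 3 to 10, 6 to 14 and 1 to 12. The 6, 12 and 9 lists became 0, 0 and 0 with an estimated correlation and 0, 1 and 0 with fry. Yellow against white gave 3 lists with the muscle score and 4 with both scores, and brown against yellow gave 5 and 2.

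Directions turned mostly for results that had not passed. As adjusted p, purine synthesis turned in brown against white at 5 FPKM (0.892), under the block (0.932), without the libraries numbered 3 (0.665), and with 1 library left out (brown 1, brown 3 or white 1; 0.312 to 0.999 over the 9). In yellow against white it turned without a filter (0.788), without white 3, yellow 1 or yellow 2 (0.379 to 0.955), and with the muscle score (0.517) and both scores (0.647), and in brown against yellow without brown 3 (0.0602 to 0.875) and with both scores (0.662). Pteridine synthesis in brown against white turned without a filter (0.74), at 5 FPKM (0.811) and with TPM (0.733). Pigment cell regulators in brown against white turned with TPM (0.733), without white 1 or white 2 (0.601 to 0.996), and with the muscle score (0.969) and both scores (0.858), and in brown against yellow without brown 3 (0.225 to 0.987). The melanin list in brown against yellow turned without a filter (0.359) and with both scores (0.999). Called lists of yellow against white turned for dermal fibroblasts without white 2 (0.226, and 0.000108 to 0.706 over the 9), glycolysis with the muscle score (0.197) and both scores (0.436), and keratinocytes with both scores (0.792). The keratinocyte score is built from that same list and removes its change by construction, so the last turn says nothing on its stability. As log2 changes, LOC113111009 turned with summed copies (-0.15 against white, -0.31 against yellow), LOC113054907 in brown against yellow with array weights (-0.11) and summed copies (-0.62), LOC113111411 there with TPM (0) and array weights (-0.11), and LOC113106593 in yellow against white with the muscle score (-0.03). Genes on fewer than 3 reads in a color were limited by depth.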

Other observations

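The tests of muscle against color, of fewer pigment cells and of ribosomal proteins relative to one another were chosen after the result was seen. In a contrast also chosen then, white against the other 6 libraries as 1 group, limma called 6 genes higher and 4 lower in brown and yellow, with 1617 at an unadjusted p under 0.05, and 7 of them were among the 15 called in a single comparison with white. A further coagulation factor XIII A chain-like copy, LOC113065965, was at 4.59 ± 1.7 FPKM in white, 0.0453 ± 0.062 in brown and 0.241 ± 0.418 in yellow (SD, n = 3; limma adjusted p = 0.0174). The protein-glutamine gamma-glutamyltransferase K-like gene LOC113040942, a relative of factor XIII A among transglutaminases, went the other way, at 0.555 ± 0.507, 8.11 ± 2.88 and 7.95 ± 4.38 FPKM (adjusted p = 0.0434).

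Regrouping the libraries argued against chance for the overlap alone, and did not exclude it there. Of 100 drawn splits, 1 (the real one) gave an overlap of 7, and the highest other was 6. The overlap was 0 without brown 1, and both comparisons share the white libraries. For the F test 5 of 100 gave 13 genes or more and the highest other gave 1957, and for white against the rest 5 of 84 gave 10 or more and the highest other gave 4431, so chance is not excluded for either. Those larger splits point to a structure of the samples, since the highest of the 84 set brown 2, white 3 and yellow 3 apart, and the next, with 1461 genes, brown 3, white 3 and yellow 3. The 10 splits of 6 libraries are too few for a share under 0.05. In them, 1, 2 and 10 splits reached the real 10, 12 and 0 genes of brown against white, yellow against white and brown against yellow, with 0, 1485 and 17 as the highest other. For brown against yellow this was fixed in advance, since every split reaches 0 genes. For lists, 9, 2 and 2 splits reached the real 6, 12 and 9, with 12, 12 and 13 as the highest other.

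Muscle transcripts varied within each color. The widest range of the muscle score within a color was 5.54, which is 2.95 times the largest difference between color means (1.88), and argues against skin color as the whole cause. Of 65 tested muscle genes outside the list, 98.5% correlated positively with the score within colors, beside 46.2% of all genes, which is consistent with a varying amount of muscle tissue in the skin pieces. The most abundant muscle gene, creatine kinase M-type LOC113049569, ran from 123 FPKM in yellow 1 to 35300 in white 3. A contribution of color to the mean level stays open.

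The 7 genes called against white in both other colors kept at least 96.2% of their log2 change with the muscle score as a covariate. They had been picked for passing without it, which favors genes with a small spread within colors, where the score varied most. The outcome was thus largely set beforehand, and no conclusion on muscle tissue is drawn from it. With the covariate, 2 falling copies missed the threshold in yellow (limma adjusted p = 0.0879), with LOC113042740 at -3.93 ± 0.50 (SE) before and -3.96 ± 0.54 after and LOC113042211 at -2.61 ± 0.33 and -2.58 ± 0.35, and residual degrees of freedom down from 6 to 5. Summed over the 8 annotated factor XIII A copies, the change was -1.47 ± 0.41 (SE) in brown and -0.92 ± 0.41 in yellow. The size of 0.92 lies within its error of the bound of 1, and that bound could not decide. The called copies held 24, 14.8 and 6.58 FPKM of a white sum of 121 ± 34 (SD), so their loss alone would move it by under 1. In brown the sum fell to 42.7 ± 11.6 FPKM, so the other copies together did not rise. This argues against reads moving between the annotated copies as the whole cause in brown. The yellow sum of 65.9 ± 25.7 FPKM leaves it open there. Of the 3 rising products with other copies, the sums of putative defense protein 3 (3.28 ± 0.28 in brown and 4.46 ± 0.28 in yellow) and of seipin (2.80 ± 0.54 and 3.88 ± 0.54, down from 4.51 ± 0.49 and 5.85 ± 0.49 for the single copy, and so no longer past the threshold) lay beyond 1 by over 2 SE in both comparisons, which argues against reads moving between copies as their whole cause. The retinol dehydrogenase 12 sum did so in yellow (2.21 ± 0.36) but not in brown (1.40 ± 0.36), so the bound did not decide for it. In FPKM that sum rose from 9.19 ± 2.46 in white to 26.9 ± 11.3 in brown (SD), and the single copy from 0.517 ± 0.328 to 17.8 ± 7.74. The other copies together therefore did not fall, which argues against reads moving between copies as its whole cause. Fewer pigment cells in white skin is a candidate explanation for the rising genes that the values could not decide. The summed reads of 9 of 13 pigment genes were lowest in white, also with any 1 library left out, though dct was so on 2 reads against 4 in yellow. The share of all genes that were lowest in white is not given here, so the count of 9 of the 13 genes has no baseline. Of the other 4, mitf (13.8 CPM in white), kit (15.2) and oca2 (0.0776) became lowest there without white 3 (9.98), white 1 (5.93) and white 1 (0), while csf1r (35.7) did not without any 1 library. The mitf sum hides a copy, LOC113096094, with 5 reads in white, 110 in brown and 60 in yellow. Cell number cannot be told apart from the level per cell in bulk tissue, and genetic background of the color lines was not tested.

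In brown 3, 7 of 186 tested ribosomal protein copies lay at least 16-fold away from all 8 other libraries, against 1 copy in yellow 2 and 0 in the rest. Each of the 5 products concerned had 1 copy higher there, such as the RPL35 copy LOC113090293 at 4390 FPKM and at most 22.7 elsewhere, but the 2 lower copies, such as LOC113038961 at 4.44 and at least 838, were both of RPL35, and the other 4 products had none. As specified before the result was seen, the test argued against reads moving between copies, since summed copies lay within 2-fold of the other libraries for 20% of the 5 products. That bound took the libraries to share a scale, and the median ratio over the 69 other ribosomal protein products in brown 3 was 2.85. Relative to it 100% of the products lay within 2-fold. For the 4 products other than RPL35 this was nearly fixed, since the risen copy held a minor part of the brown 3 sum, such as 991 of 4710 FPKM for RPL23A. Only RPL35 (4390 of 6980) could decide. A copy or sequence variant in that sample, which could move reads between copies, therefore stays open. The 2 tests disagree, the second could decide for RPL35 only, and the other 4 products had no copy that fell by 16-fold.

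On chromosome 2, between 19416225 and 19678871, LOC113119323 and an unannotated transcript both differed between brown and white, in opposite directions, with log2 changes of -3.83 and 2.26. With a pseudocount of 0.1 the transcript did not pass (limma adjusted p = 0.0874). Their nearness was seen after the calls, and whether it exceeds chance was not tested.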
